A study of Sus scrofa with 9 samples.

How the data were processed

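RNA-seq libraries of pig blastocysts were described by the labels as not injected, injected with control siRNA or injected with INO80 siRNA, with 3 samples in each group. Values are FPKM per gene locus and per transcript, as the authors deposited them. Transcript positions, exonic lengths and exon numbers came from the same deposited table. Per the submitters' processing notes, fastp, HISAT2, StringTie and edgeR were used, and HOMER and ChIPseeker are also named; no versions are given, and their order, filters, annotation release and strand setting are not given in the sources used here. The same notes name GRCh38.p10, a human build, while gene IDs are pig Ensembl IDs. Transcripts on chromosome 1 end as far as 315248247, beyond the last RefSeq gene end of 274280750 on that chromosome of Sscrofa11.1, so that assembly was used for no position. Without a stated strand setting, reads of a gene and of its antisense partner cannot be told apart.

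Groups were taken from the siRNA characteristic of each sample. The 3 samples with the INO80 siRNA characteristic have titles naming a water sham injection. Columns named for uninjected embryos matched the titles of the uninjected samples, and columns named INO80 siRNA were assigned to that group without a sample of their own. Columns named for a water sham share their name with samples whose characteristic is INO80 siRNA, and no column is named for control siRNA. They were therefore used in no step, which leaves out 3 FPKM columns of the gene table and 3 of the transcript table. The 9 coverage columns of the transcript table were not used either, since columns tied only to a group were kept for 1 measure. The planned comparisons of INO80 siRNA with control siRNA and of control siRNA with uninjected embryos, and the overlap of calls between comparisons, were not analysed here. The shared fit of 9 libraries planned in advance became a fit of 6, the isoform test was moved to the comparison with uninjected embryos, and list members were ranked in that comparison.

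The gene table held 88800 loci, of which 2038 were at 0 in the 6 libraries and 45478 had no gene name, and the transcript table held 147461 transcripts. Of 7176 Ensembl gene IDs used as names, 2230 matched a symbol. A locus was called annotated where a transcript matched or shared a splice structure with a known transcript on the same strand (17065 loci); other loci lay outside genes, within introns, antisense to genes or in other overlaps. A name carried by several loci was represented by 1 annotated locus, chosen first by holding a listed Ensembl transcript and then by transcript length. Gene FPKM equalled the length-weighted sum of transcript FPKM up to 1 length per locus at 100.0% of 59641 loci checked, within a relative tolerance of 0.01. Shares of signal within a library were computed from transcript FPKM times length. FPKM is relative to the whole library, so values of annotated loci depend on the rest of it.

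Because the files used hold no counts, differences were tested with limma 3.58.1 in R 4.3.3 (trend and robust moderation, two-sided) on log2(FPKM + 1), over loci with a mean of at least 1 FPKM in at least 1 group, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate those of low genes. Gene sets were tested with camera at a preset correlation of 0.01 on 20 lists, with an estimated correlation and fry as alternatives; a list needed 3 measured members. The lists covered the INO80 complex, other chromatin remodellers, tight junctions, adherens junctions and desmosomes, polarity, ion and water transport, trophectoderm, epiblast, primitive endoderm, Hippo, maternal transcripts, apoptosis, DNA repair, cell cycle, interferon response, stress, oxidative phosphorylation, glycolysis, cumulus and granulosa cells, and blood and immune cells. Single values were compared with exact permutation tests. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

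The design, lists, alternatives and rule for named genes were fixed before the data were examined. The rule named INO80, a fixed set of junction, pump and lineage genes, up to 4 members with the smallest p of each list, and genes with recognised symbols, a mean of at least 1 FPKM and no overlap between groups, by size of change where they passed and otherwise the 5 with the smallest p in each direction, said not to pass; only examples of the list members are described. Some genes that the rule names are not reported here; they remain in the counts and set tests. The fit to annotated loci, the annotated background of the set test, array weights, the isoform test against uninjected embryos and the tests of KEGG terms were added after first fits had been seen. Alternatives were limma without trend, quantile normalization, scaling to the median library, no filter, a minimum of 5 FPKM, a pseudocount of 0.1, the replicate number as a block, a stricter adjusted p of 0.01, a minimum log2 fold change of 1, and leaving out each library in turn.

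The fits were tested on simulated values for this comparison, with 200 changed loci. These were drawn only from loci of higher mean values, so recovery at low genes such as INO80 was not tested. Among 64076 loci, 0% of changes of 2 on the log2 scale were recovered, 30% of changes of 4, 58% of changes of 6 and 80% of changes of 8. Among 8778 annotated loci the shares were 48%, 96%, 98% and 100%. There were 2 false calls among all loci and 11 among annotated loci, beside the 200 changed loci. At a threshold on adjusted p, false calls grow with the number of true ones. These counts are therefore no measure for the 1 call of the real data. Recovery at such a threshold also rises with the number of changed loci. The shares recovered hold for 200 changed loci and do not give the power where few loci change. The set test at the preset correlation recovered 5 of 5 simulated sets shifted by -1 among 20 sets of annotated loci, with 0 false calls. Simulated loci varied independently of each other, and the background was annotated loci. The 0 false calls therefore do not vouch for the preset correlation where genes vary together, nor for calls against all loci.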

Results

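RNA was sequenced from pig blastocysts, the embryo stage at which an outer epithelium, the trophectoderm, encloses a fluid-filled cavity. The labels describe 9 samples in 3 groups of 3: embryos that were not injected, embryos injected with a control siRNA and embryos injected with an siRNA against INO80, the ATPase of a chromatin remodelling complex. Table columns could be tied to the labels for 6 libraries, 3 uninjected and 3 labelled INO80 siRNA, and these are compared here. The labels do not say whether libraries of a group came from separate embryo pools, so p-values measure the spread between these samples, which may be technical. INO80 siRNA libraries are numbered 1 to 3 as in the column names, which no label ties to a sample. No read counts were used, so sequencing depth and counting intervals are not given. Positions are those of the tables, whose pig genome build is not given in the sources used here.

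The targeted transcript was examined first. INO80 (locus MSTRG.4659, chromosome 1, 145362748 to 145504969, transcripts of up to 36 exons) measured 0.737, 1.09 and 1.92 FPKM in the uninjected libraries and 0.331, 1.37 and 2.18 FPKM in the libraries labelled INO80 siRNA. The means were 1.25 ± 0.607 and 1.29 ± 0.927 FPKM (SD, n = 3 each), and the groups were not separated (two-sided exact permutation p = 1; the smallest p that 3 against 3 allows is 0.1). The log2 fold change was -0.03 on the log2(FPKM + 1) scale (SE 0.561, limma adjusted p = 0.992). It turned positive without uninjected library 3 (0.18) and without INO80 siRNA library 1 (0.32). With a pseudocount of 0.1 the difference was -0.16 with a 95% interval of -2.45 to 2.13. Given the spread between these libraries, neither a halving nor a doubling was excluded. A reduced INO80 level was therefore not visible in these libraries, and every direction below is that of libraries labelled INO80 siRNA.

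The comparison of libraries labelled INO80 siRNA with uninjected embryos asks how embryos injected against INO80 differ from embryos left alone, and it cannot separate the siRNA from the injection. Neurolysin (NLN, an oligopeptidase; ENSSSCG00000016778, locus MSTRG.37160, chromosome 16, 47574646 to 47681209) was the 1 annotated locus that changed. It fell from 79.9 ± 29.4 FPKM in uninjected embryos to 2.42 ± 1.46 FPKM (SD, n = 3 each), a log2 fold change of -4.58 (SE 0.489, limma adjusted p = 0.0088 among 8778 annotated loci), and was lower in 3 of 3 libraries. The restriction to annotated loci was chosen after seeing the data. Among all 64076 loci the adjusted p of NLN was 0.291 and 0 loci passed in limma, the lowest adjusted p being 0.171. At an unadjusted p below 0.05 there were 3032 loci, 2418 higher and 614 lower, where 3204 were expected by chance. Quantile normalization gave 1707 higher and 1375 lower, and scaling to the median library 2055 and 1096. Quantile normalization over all loci gives the libraries the same distribution, which balances the changes in advance. Without uninjected library 3 the counts were 1596 higher and 1286 lower. Higher loci outnumbered lower ones in each fit that left out 1 library. The size of the excess of higher loci thus depends on the scaling and on single libraries. Among annotated loci there were 466, of which 83 were higher and 383 lower, where 439 were expected. Scaling to the median library gave 48 and 586, so the size of this lean depends on the scaling too. Quantile normalization within annotated loci gave 170 higher and 189 lower, with a median log2 fold change of -0.01. That setting gives all libraries the same distribution of annotated values. It balances the changes in advance and cannot show whether the lean holds. The 2 groups did not overlap at 11.2% of all loci and 10.7% of annotated loci, where chance gives 10%. The NLN call was lost without uninjected library 1 (adjusted p = 0.0778), without INO80 siRNA library 3 (0.0854) and with no filter on low values (0.223), within a range of 0.0046 to 0.223 over its alternatives.

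**Figure D1:**
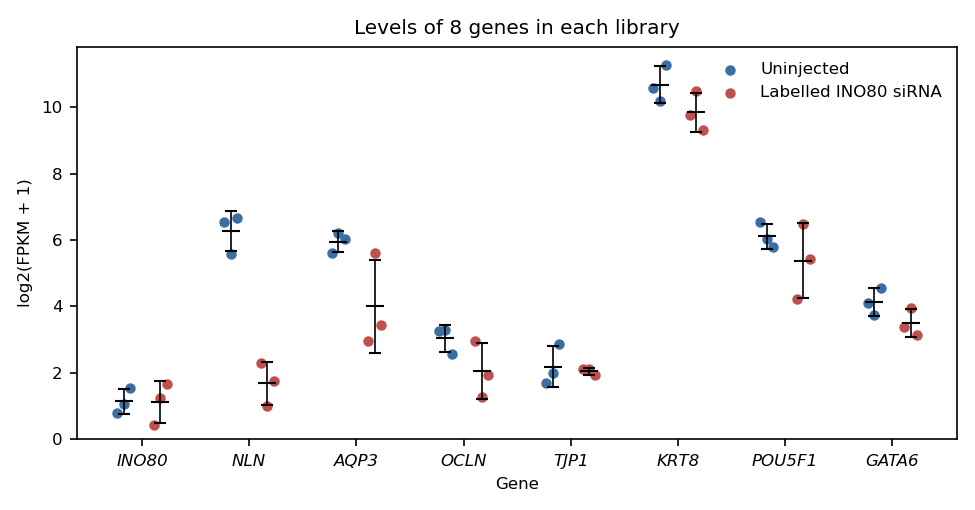
Levels of 8 genes as log2(FPKM + 1), vertical axis, in each uninjected library (blue points) and each library labelled INO80 siRNA (red points), with the mean and SD of 3 libraries as a bar and whiskers. The 2 groups overlap for INO80 and stand apart for NLN, whose mean was 79.9 FPKM in uninjected libraries and 2.42 FPKM in the others.

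Other annotated genes stood apart between the groups without passing the test. CLN6, an endoplasmic reticulum membrane protein tied to lysosomal storage disease, measured 58.7 ± 42.0 FPKM in uninjected libraries and 6.1 ± 4.19 FPKM in the libraries labelled INO80 siRNA (n = 3 each). FUT1, a fucosyltransferase, measured 5.03 ± 1.55 and 0.624 ± 0.526 FPKM, SPSB2 4.3 ± 1.4 and 0.441 ± 0.37 FPKM, and CELA1, an elastase, 21.9 ± 6.88 and 4.82 ± 0.181 FPKM. In the other direction, the protease inhibitor SLPI measured 30.2 ± 22.6 FPKM in uninjected libraries and 130.0 ± 28.7 FPKM in the others, SH3BGRL 2.91 ± 1.64 and 16.4 ± 10.7 FPKM, and MEIG1 0.762 ± 0.668 and 5.41 ± 0.687 FPKM. SPA17 measured 0.291 ± 0.163 and 3.23 ± 1.19 FPKM and PTMAP 0.769 ± 0.428 and 6.88 ± 4.75 FPKM. Adjusted p-values of these 9 genes were 0.743 to 0.769 in limma. Of 2418 higher and 614 lower loci at an unadjusted limma p below 0.05, 1507 and 301 lay outside genes, as did 33270 of all 64076 loci tested. The loci named here are the ones with recognised symbols and the smallest p. A locus within ATP2B1, chromosome 5, 97605152 to 97613074, measured 2.18 ± 0.493 and 398.0 ± 241.0 FPKM (limma adjusted p = 0.171). Loci antisense to CEP85L and RAE1 and one overlapping TMED3 also had higher values, and loci overlapping ST13 or within introns of FRMPD2, SCLT1 and AP2A1 lower values, with adjusted p-values of 0.247 to 0.828.

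Genes of the barrier and fluid transport of the blastocyst were examined as lists fixed before the data were examined. Of 9 measured genes of ion and water transport, 0 passed, over all loci or adjusted over the list alone (lowest 0.0774). The water channel AQP3 (chromosome 10, 37307556 to 37313382) measured 61.8 ± 12.9 FPKM in uninjected libraries and 21.4 ± 22.7 FPKM in libraries labelled INO80 siRNA (n = 3 each). AQP11 measured 6.74 ± 5.08 and 1.01 ± 0.859 FPKM, while the pump regulator FXYD5 measured 0.205 ± 0.302 and 3.46 ± 3.53 FPKM. These 3 genes had unadjusted limma p-values of 0.0311 to 0.0388 and an adjusted p of 0.84. ATP1B1, a sodium pump subunit, measured 2.9 ± 2.72 and 1.85 ± 1.35 FPKM. Of 16 measured tight junction genes 0 passed by either adjustment. The junction protein OCLN measured 7.4 ± 2.18 and 3.68 ± 2.79 FPKM, CLDN7 119.0 ± 85.5 and 55.4 ± 36.5 FPKM, and the scaffold TJP1 3.83 ± 2.15 and 3.13 ± 0.295 FPKM. CLDN6 measured 111.0 ± 120.0 and 99.1 ± 37.6 FPKM. CLDN4 was listed at 0 in all 3 uninjected libraries and in INO80 siRNA libraries 1 and 2, and at 162 FPKM in library 3. Of 12 adherens junction and desmosome genes and 11 polarity genes 0 passed by either adjustment; the catenin CTNND1 measured 9.37 ± 0.811 and 5.08 ± 1.45 FPKM and the membrane linker EZR 145.0 ± 41.7 and 73.0 ± 30.3 FPKM.

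Lineage genes gave the same picture of values without calls. Of 16 measured trophectoderm genes 0 passed by either adjustment: the keratin KRT8 measured 1720.0 ± 669.0 FPKM in uninjected libraries and 975.0 ± 412.0 FPKM in libraries labelled INO80 siRNA, GATA3 20.5 ± 11 and 13.3 ± 13.3 FPKM, TEAD4 10.6 ± 2.39 and 9.19 ± 7.15 FPKM, and CDX2 0.315 ± 0.283 and 1.16 ± 1.72 FPKM. Of 14 epiblast and pluripotency genes 0 passed; TDGF1, a Nodal co-receptor, measured 27.0 ± 4.37 and 8.55 ± 3.78 FPKM (limma adjusted p = 0.84, 0.0254 before adjustment) and POU5F1 69.8 ± 19.4 and 49.3 ± 36.1 FPKM. Of 8 primitive endoderm genes 0 passed, with GATA6 at 17.1 ± 5.24 and 10.6 ± 3.49 FPKM and GATA4 at 1.4 ± 1.47 and 0.45 ± 0.34 FPKM. CDH1, ATP1B3 and NANOG were not matched to an annotated locus here, and SOX2 lay below the filter. Of 12 INO80 complex genes 0 passed; INO80C measured 18.5 ± 5.51 and 9.53 ± 3.32 FPKM and RUVBL1 41.5 ± 12.6 and 23.8 ± 4.5 FPKM. Of 13 Hippo pathway genes 0 passed, with TEAD1 at 6.4 ± 1.79 and 3.74 ± 0.963 FPKM, and of 17 other chromatin remodellers 0 passed, with CHD1 at 6.76 ± 0.271 and 4.2 ± 1.58 FPKM.

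Lists of cell state and of other cell types also held 0 calls by either adjustment. They had 13 stress, 14 apoptosis and p53, 15 DNA repair, 16 cell cycle, 6 interferon, 24 oxidative phosphorylation and 13 glycolysis genes measured. The glycolytic enzyme ENO1 measured 167.0 ± 106.0 FPKM in uninjected libraries and 43.1 ± 10.5 FPKM in libraries labelled INO80 siRNA, and the glutathione-degrading enzyme CHAC1 11.9 ± 13.7 and 1.58 ± 2.49 FPKM; their unadjusted limma p-values were 0.0419 and 0.0414. BID measured 22.0 ± 6.77 and 12.1 ± 6.57 FPKM, MCM3 20.2 ± 5.67 and 8.26 ± 6.42 FPKM, IRF7 1.59 ± 0.79 and 0.252 ± 0.199 FPKM, ATP5B 1090.0 ± 208.0 and 652.0 ± 257.0 FPKM, and BRCA1 0.74 ± 0.35 and 1.24 ± 0.0593 FPKM. Of 12 maternal oocyte transcripts, 9 had positive log2 fold changes; UCHL1 measured 2.52, 5.74 and 1.98 FPKM in uninjected libraries and 2.38, 12.3 and 111.0 FPKM in INO80 siRNA libraries 1 to 3. Of 5 blood and immune genes, HBB measured 0.152, 1.03 and 0.0651 FPKM in uninjected libraries and 0.134, 23.6 and 0.0611 FPKM in INO80 siRNA libraries 1 to 3, and 2 cumulus and granulosa genes were measured, SERPINE2 at 20.8 ± 5.91 and 12.1 ± 4.89 FPKM and FST at 33.0 ± 33.5 and 12.6 ± 4.92 FPKM.

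As sets against all loci, 14 of the 19 lists tested were called lower in the libraries labelled INO80 siRNA (limma camera, preset correlation 0.01). They included trophectoderm (median log2 fold change -0.66, adjusted p = 0.0022), adherens junction and desmosome (-0.46, 0.00342), ion and water transport (-1.15, 0.00805) and tight junction (-0.33, 0.0149). With an estimated correlation 0 lists were called, the adjusted p of these 14 being 0.212 to 0.373. Against annotated loci only, a background added after seeing the data, 0 were called (lowest adjusted p = 0.294). By fry, which tests each list against no change and not against other loci, 0 were called (lowest adjusted p = 0.443 in the fit to all loci and 0.403 in that to annotated loci). Every list member is an annotated locus, and the median log2 fold change was -0.22 over annotated loci and 0.23 over all loci. Without uninjected library 3, 0 lists were called against all loci, and without uninjected library 1 or INO80 siRNA library 1, 9 were called each time. Quantile normalization over all loci shifted the median of annotated loci to -0.48 and that of all loci to -0.02, and scaling to the median library shifted them to -0.39 and 0.06. These medians were -0.03 and 0.1 with no filter, and -0.31 and 0.31 with a minimum of 5 FPKM. The offset between them thus depends on the filter too.

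**Figure D2:**
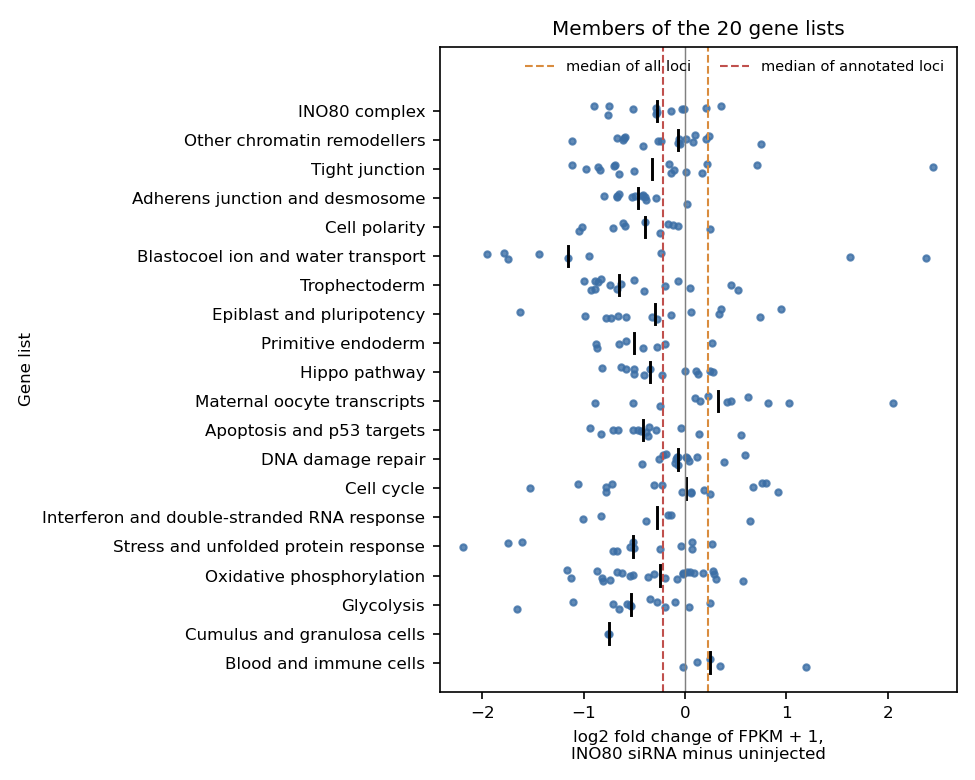
Log2 fold change of FPKM + 1 (INO80 siRNA minus uninjected, horizontal axis) of each measured member (points) of 20 gene lists, with each list's median as a black bar. Dashed lines mark the medians of all loci (0.23) and of annotated loci (-0.22); most list medians lie near or below the latter.

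Signal, taken as transcript FPKM times length, was spread over the annotation differently from library to library. Annotated transcripts took 67.7%, 61.0% and 74.6% of it in uninjected libraries 1 to 3 and 65.3%, 71.6% and 50.3% in INO80 siRNA libraries 1 to 3. Transcripts outside annotated genes took 17.6% ± 3.95 and 20.9% ± 6.42 (SD, n = 3 each; two-sided exact permutation p = 0.6, smallest possible 0.1). Over annotated loci the mean correlation between libraries, across genes that are not independent replicates, was 0.888 within groups and 0.888 between groups, and the closest pair, uninjected library 3 and INO80 siRNA library 2 (0.931), belonged to different groups. That INO80 siRNA library correlated at 0.921, 0.892 and 0.931 with uninjected libraries 1 to 3. With INO80 siRNA libraries 1 and 3 it correlated at 0.873 and 0.869. Without it, 182 annotated loci were higher and 628 lower at an unadjusted limma p below 0.05.

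**Figure D3:**
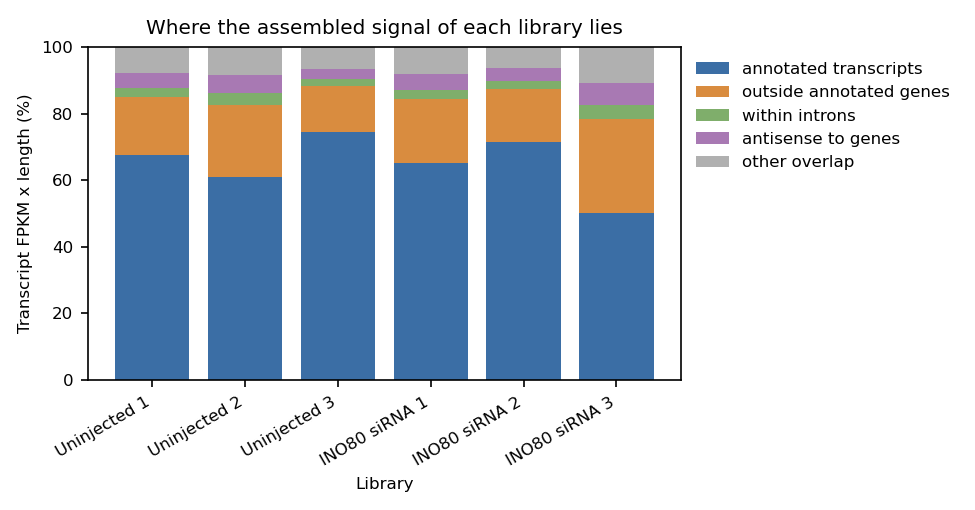
Share of transcript FPKM times length (%, vertical axis) that lay in annotated transcripts, outside annotated genes, within introns, antisense to genes and in other overlaps, 1 stacked bar per library. INO80 siRNA library 3 had the smallest annotated share of the 6 (50.3%) and uninjected library 3 the highest (74.6%).

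In the isoform table, 6 of 104522 transcripts passed (limma, 3 higher and 3 lower), and 0 passed in any fit that left out 1 library. Transcripts antisense to IL13RA2 on chromosome X, a receptor subunit for interleukins, lay on both sides. MSTRG.89799.2 was listed at 0 in all 3 uninjected libraries and at 534, 488 and 769 FPKM in INO80 siRNA libraries 1 to 3, while MSTRG.89799.3, which starts within a few bases of it, measured 568, 909 and 454 FPKM and then 0.097, 0.17 and 1.19 FPKM. A transcript of NPC2, a lysosomal cholesterol carrier, measured 242, 226 and 541 FPKM in uninjected libraries and 0.0779, 0.224 and 1.23 FPKM in the others. The whole NPC2 locus measured 544, 312 and 1030 FPKM in uninjected libraries and 121, 388 and 141 FPKM in INO80 siRNA libraries 1 to 3, so the groups overlapped there. Whether reads were assigned differently between transcripts of a locus was not tested for the called transcripts. A transcript antisense to STC1 and one of ENSSSCG00000028369 were listed at 0 in all uninjected libraries and at 150 to 644 FPKM in the others, and an unnamed transcript on chromosome X measured 119 to 307 FPKM in uninjected libraries and at most 0.118 FPKM in the others. Names of these transcripts fell outside the rule for named genes and were chosen after their values were seen.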

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

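Apart from the counts of calls over other splits of the libraries in the last paragraph, the tests of explanations in this part, that of a swap among them, were chosen after the results they address had been seen, and how overlapping groups were read was settled after the values were known. Of the split counts, those for annotated loci, for isoforms and for lists against annotated loci rest on fits added after seeing first fits.

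In INO80 siRNA library 3, 28.1% of signal (transcript FPKM times length) lay outside annotated genes, above the 13.7% to 21.6% of the uninjected libraries, a signal outside the annotated genes that the comparisons of gene lists rest on. With it went a pattern over all loci: the median log2 fold change was -0.22 for annotated loci and 0.353 for loci outside genes, a gap of 0.57. Without that library the gap was 0.41, with medians of 0.09 outside genes and -0.32 at annotated loci; leaving out uninjected library 3 gave 0.38. The gap stayed above 0.5 times its size, which was first set as evidence against this library as the main source. It did so by less than its spread over the 6 fits that leave out 1 library (SD 0.14). Reading the gap by that spread was settled after the values were known. These fits share libraries, so the SD is no sampling error of the gap. It therefore cannot be told apart whether this library is the main source. A rise in transcription outside genes after INO80 siRNA stays open too: the share was above every uninjected library in 1 of 3 libraries, and although that overlap was first set as evidence against such a rise, 3 libraries against 3 do not exclude a small one.

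Mitochondrial transcripts took 1.75% of signal in INO80 siRNA library 1, above the 0.05% to 1.2% of the uninjected libraries. INO80 siRNA libraries 2 and 3, at 0.09% and 0.17%, lay within that range.

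INO80 was not lower in the libraries labelled INO80 siRNA. A level too low or too variable to show a fall is a candidate explanation, since the 95% interval of the log2 difference reached down to -2.45, beyond a halving. Reads split over the 8 loci that carry the name remain open. Summed over 12 same-strand transcripts, 1 of 3 INO80 siRNA libraries lay below every uninjected library. The means were 24 ± 11.4 and 23.1 ± 7.09 FPKM times kilobases in INO80 siRNA and uninjected libraries. Overlap was first set as evidence against such a split. The sum took only transcripts classed as sharing a splice structure or overlapping exons on the same strand. It therefore need not cover all 8 loci. A swap of 1 library between the groups cannot be told apart from chance or another structure of the samples, because 3 of the 9 other splits had more annotated loci at an unadjusted p below 0.05 than the 466 of the labelled groups, up to 852. The highest of these counts came from the split that groups INO80 siRNA library 2 with uninjected libraries 1 and 3. That count was picked after all had been seen, and whether it exceeds chance was not tested. A mix-up of whole groups between labels and columns also stays open and was not tested, since the samples labelled INO80 siRNA have titles that name a water sham. An siRNA effect on protein or at an earlier stage was not tested.

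For NLN, assignment of its reads to another transcript of the region is argued against by the data: summed over the 11 transcripts that overlap the locus, the signal lay below every uninjected library in 3 of 3 libraries labelled INO80 siRNA (12.2 to 26.8 against 255 to 539 FPKM times kilobases). Whether 1 library sets the call cannot be told apart from a stable difference, since the adjusted p among annotated loci reached 0.0854 without INO80 siRNA library 3 and 0.0778 without uninjected library 1, while the log2 fold change stayed between -4.93 and -4.23. An effect of the siRNA or of the injection was not tested separately and stays open.

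With 10 splits of the 6 libraries no share under 0.05 can be reached. Over all loci, 0 were called for the labelled groups, a count that all 10 splits reached, and 2 in the highest other split. Among annotated loci 1 was called and 4 in the highest other split, with 8 splits calling at least 1. For isoforms the counts were 6 and 6, reached by 2 splits, and for gene lists against all loci 14 and 7, reached by 1 split. Against annotated loci 0 lists were called for the labelled groups and 4 in the highest other split.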

How the results depend on the processing

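Alternatives marked as added in the processing account, among them every fit restricted to annotated loci, were chosen after seeing the data; the cause of the changes below was not tested unless stated. Over all loci 0 were called under every alternative run (lowest adjusted p 0.0607 to 0.733) except that testing annotated loci only gave 1. Among annotated loci the count of 1 became 0 with no filter and ranged from 0 to 3 when each library was left out: 0 without uninjected library 1 or INO80 siRNA library 3, 2 without uninjected library 2 or 3, and 3 without INO80 siRNA library 2. The 6 isoforms became 0 with no filter, 0 with the replicate number as a block and 0 without each library in turn. The 14 gene lists became 0 with an estimated correlation, 0 against annotated loci and 0 there with an estimated correlation, and by fry, a test against no change, 0 in the fit to all loci and 0 in that to annotated loci; leaving out each library gave 0 to 13 against all loci (0 without uninjected library 3, 9 without uninjected library 1 or INO80 siRNA library 1) and 0 to 3 against annotated loci (1 without uninjected library 2, adherens junction and desmosome; 3 without INO80 siRNA library 2, of which trophectoderm and oxidative phosphorylation were called lower and maternal oocyte transcripts, outside the 14, higher). Against annotated loci without INO80 siRNA library 3, maternal oocyte transcripts turned lower (camera adjusted p = 0.886) and oxidative phosphorylation higher (0.196). Neither was called there. KEGG terms went from 9 to 0 with an estimated correlation and ranged from 1 to 16 without each library (1 without uninjected library 3, 4 without uninjected library 2, 16 without INO80 siRNA library 2). The log2 fold change of INO80 ranged from -0.31 to 0.32 without each library and was 0.0015 for the sum over its same-strand transcripts; a minimum of 5 FPKM removed the locus. Named genes that did not pass turned direction as follows, each without 1 library: TJP1 (-0.39 to 0.20), CLDN6 (-0.59 to 1.74), ATP1B1 (-1 to 0.30), TEAD4 (-0.94 to 0.07), S100A9 (-0.54 to 1.26), LYZ (-0.35 to 1.10), CD68 (-0.65 to 0.68), FST (-1.71 to 0.10), EIF2AK2 (-0.85 to 0.10) and APOA2 (-1.35 to 0.02). With a pseudocount of 0.1, ATP1B1 was 0.05 and S100A9 -0.12; with array weights, LYZ was -0.04 and CD68 -0.01; CD68 was -0.19 with quantile normalization and -0.07 with scaling to the median library. For the 6 headline results, 47 of 84 values under an alternative stayed the same within a set margin. Another 34 moved and 3 turned direction, all in 1 of these results. Of 1649 values of reported single genes and isoforms under an alternative, 1577 kept direction and side of the threshold, 51 kept direction and lost the call and 21 turned. Most of these genes were not called with the main settings, so keeping the side of the threshold says little for them. The 51 losses fall on the few that were called. The replicate numbers of the INO80 siRNA libraries come from column names that no label ties to a sample, and they did not pair the libraries: residuals of same-numbered libraries correlated at 0.063, -0.207 and -0.124. With that number as a replicate block, 0 of all loci, 1 annotated locus, 0 isoforms, 10 gene lists and 8 KEGG terms were called, and against annotated loci 1 list (maternal oocyte transcripts, higher). Alternatives for comparisons with control siRNA, for counts and for the overlap of calls were not run. In simulated data of this size, changes were placed only in loci of higher mean values. Of changes of 2 on the log2 scale, 0% were recovered over all loci and 48% over annotated loci. These shares hold for 200 changed loci and do not give the power where few loci change. Smaller changes were not simulated.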

Other observations

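The tests of KEGG terms were chosen after the first results had been seen. Lysosomal genes formed the term with the smallest p among 198 terms in the deposited annotation: 68 of 74 annotated loci had negative log2 fold changes in libraries labelled INO80 siRNA, with a median of -0.62 where all annotated loci had -0.22 (limma camera, preset correlation, adjusted p = 9.36e-06; adjusted p = 0.946 with an estimated correlation). The ganglioside activator GM2A measured 305.0 ± 197.0 FPKM in uninjected libraries and 70.9 ± 52.4 FPKM in the others (SD, n = 3 each), the hexosaminidase subunit HEXA 32.2 ± 8.41 and 13.2 ± 5.99 FPKM, the channel MCOLN1 18.0 ± 7.98 and 5.32 ± 2.73 FPKM, and NPC2 630.0 ± 368.0 and 217.0 ± 149.0 FPKM. None of these 4 genes passed on its own (limma adjusted p = 0.91). Without INO80 siRNA library 3 the adjusted camera p of the term was 0.000391. Values of this term without each other library, uninjected library 3 among them, are not given here.

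In all, 9 terms were called with the preset correlation, 8 lower and 1 higher, and 0 with an estimated correlation (lowest adjusted p = 0.946). The citrate cycle had 23 of 24 loci with negative values (median -0.66, adjusted p = 0.00462), among them the dehydrogenases MDH2 at 145.0 ± 49.1 and 51.6 ± 32.9 FPKM and IDH1 at 103.0 ± 23.3 and 49.6 ± 19.1 FPKM (SD, n = 3 each). N-glycan biosynthesis had 29 of 34 (median -0.65, adjusted p = 0.0189), among them the oligosaccharyltransferase subunits RPN1 at 37.0 ± 6.99 and 12.7 ± 4.85 FPKM and RPN2 at 210.0 ± 35.1 and 115.0 ± 5.31 FPKM. Without INO80 siRNA library 3, 9 terms were called, of which 2, the lysosome and N-glycan biosynthesis (adjusted p = 0.00705), were among those 9; the citrate cycle was not (0.0691). The other 7 were all called higher: ribosome, which then had the smallest adjusted p (3.45e-10), oxidative phosphorylation (0.000146; lower and not called with all libraries, 0.917), cardiac muscle contraction and 4 disease terms. The count was 1 without uninjected library 3, 4 without uninjected library 2 and 16 without INO80 siRNA library 2. The design's 10 splits cannot give a share under 0.05; 5 of them called at least 9 terms, and the highest other split called 11.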
